A study of Mus musculus with 9 samples.

How the data were processed

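Messenger RNA of 9 mouse liver samples was sequenced, in 3 groups of 3 (WT with NC, WT with CCl4, KO with CCl4), and each sample was placed by its title in the labels. The authors deposited whole-number counts per gene, per the file headers, made from reads aligned with HISAT2 2.0.4 and processed with StringTie 1.3.0 against mm10 (GRCm38.p4), per the submitters' processing notes. The same table holds FPKM, per the file headers, and within a gene the authors' FPKM were proportional to the count divided by the library's total count, to within 0.002% over 9282 genes with at least 50 counts in every library. Which tool counted the reads, its strand setting, its treatment of reads that fit several genes and the annotation release are not given in the sources used here.

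These settings limit some values. Reads of near-identical copies (Saa1 and Saa2, the Orm, Cyp2c, Cyp4a and Mup families) may have been divided between them, so their separate values are uncertain, as are those of overlapping and antisense genes, since the use of strand is not stated. The table lists 34745 genes, of which 14141 had no count in any library. Symbols stored as dates (27) were restored from the gene identifiers. Of the identifiers 34267 (98.6%) were found in GENCODE M21, and of these 99.9% overlapped the gene there. Gene positions are those of the deposited table, in mm10.

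Total counts were 16447353, 16782580, 19636431 in WT NC replicates 1, 2 and 3, 16858562, 17478661, 16790695 in WT CCl4 replicates 11, 12 and 13, and 19959409, 18565612, 20373585 in KO 72, 75 and 79. A floor of 3 counts in 1 library stood for 0.147 to 0.182 CPM of the total. Floors and the 95% intervals of ratios (exact binomial, on counts pooled over a group) cover counting error only. The labels do not state that the samples of a group came from separate animals, so p-values measure the spread between these samples. Pairs of libraries within a group differed by 13.1 to 174.2 times the sampling noise (chi-square over degrees of freedom), so none was counted as a repeat of another.

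Differential expression was tested on the counts with edgeR 4.0.16 in R 4.3.3, with TMM normalisation, filterByExpr (14134 genes kept), a quasi-likelihood fit with a mean for each group over all 9 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05. The biological coefficient of variation was 0.312 and the prior degrees of freedom 3.19. The standard error of a log2 fold change was its size divided by the square root of the quasi-likelihood F statistic. CPM used TMM-scaled library sizes, and log2 CPM a prior count of 2. The comparisons were CCl4 against NC in WT, KO against WT under CCl4, and KO with CCl4 against WT with NC. The 38 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 37 lists with at least 5 genes tested. The remaining list, of sex-chromosome genes, had 4 tested, and it was used as a check of the animals' sex. Overlaps between comparisons were set beside the overlap of independent lists and 20 simulations of unchanged groups that shared the WT CCl4 libraries.

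Gene lists, comparisons, tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named 10 genes in every comparison whatever their values. It added the 6 largest rises and falls in each of the first 2 comparisons (3 in the last) among genes past the threshold, with a mean of at least 5 CPM in the higher group, no overlap of the groups' libraries, and no predicted-gene, immunoglobulin, T cell receptor or Mup symbol. It further took the 2 called members with the smallest p of each list past camera, and the 5 clearest genes called in opposite directions in the first 2 comparisons. A few results of named genes are not reported here.

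Alternatives were DESeq2 1.42.0 (Wald test), its size factors in the edgeR fit, no filter on low counts, limma with trend on log2(FPKM + 1) for genes at 1 FPKM or more in 3 libraries, a fit of only the 6 samples compared, a test against a fold change of 1.5 (glmTreat), and each replicate left out in turn. For lists, camera with an estimated correlation and fry were tried. Leaving out the 13 mitochondrial genes, and counting list members without KO 75, were added after seeing the data. On simulated counts for KO against WT under CCl4 (14134 genes, 200 changed, 3 runs), the test recovered 11.3% of genes changed 2-fold and 59% of those changed 4-fold, and 4.5% of the genes called were unchanged. A list raised on purpose was called in 3 of 3 runs, with 0 other lists called. The share of the CCl4 change left was checked in a separate simulation, in which every changed gene kept 50% of its change in KO. It was measured there as 51.4%, and genes that keep unlike shares were not simulated. The simulated genes varied independently of each other. These runs therefore could not show false list calls that come from correlated genes.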

Results

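Gene expression was measured by RNA sequencing of messenger RNA in 9 liver samples of 12-week-old C57BL/6 mice, for which the labels also give hepatocyte as the cell type. The samples form 3 groups of 3. The first is labelled WT with the treatment NC, the second WT with CCl4 and the third KO with CCl4. The labels' WT and KO were read as the series' Tgfbr2f/f animals, which carry a floxed Tgfbr2 gene, and its Tgfbr2HKO animals. How HKO was made and what NC stands for are not given in the sources used here. Carbon tetrachloride (CCl4) is a solvent that hepatocytes turn into a toxic radical, and repeated doses are a standard way to scar the rodent liver. It was injected at 0.25 ml per kg, 2 times a week for 4 weeks. The libraries held between 16447353 and 20373585 counts each, and between 15932 and 17614 genes were detected per library. Mitochondrial genes took 10.6% ± 1.46 of the counts in the WT NC libraries, 25.7% ± 0.49 in the WT CCl4 libraries and 20.2% ± 0.86 in the libraries labelled KO (SD, n = 3 each). No KO sample without CCl4 was analysed here, so whether the response to CCl4 depends on genotype could not be tested as an interaction.

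The targeted gene, Tgfbr2, encodes the type 2 receptor for TGF-beta (gene identifier ENSMUSG00000032440, chromosome 9, 116087698 to 116175363, minus strand, mm10). It stood at 31.5, 30.2 and 38.6 CPM (counts scaled to a common library total) in WT NC replicates 1, 2 and 3, and at 127, 90.5 and 75.2 CPM in WT CCl4 replicates 11, 12 and 13. Among the libraries labelled KO it stood at 23.6 CPM in KO 72 and 28.3 CPM in KO 79. In the library labelled KO 75 it stood at 70.0 CPM, close to WT CCl4 replicate 13. Tgfbr2 differed between KO CCl4 and WT CCl4 by a log2 fold change of -1.26 ± 0.39 (SE), which did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0759). Without KO 75 it was -1.91 (adjusted p = 0.0011 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The gene total does not show whether an exon is missing, and other cells than hepatocytes also express Tgfbr2.

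The library labelled KO 75 also stood apart from KO 72 and KO 79 over all genes. On the first principal component of log2 CPM, which held 73.7% of the variance, the WT NC libraries lay between -114.2 and -104.3 and the WT CCl4 libraries between 67.6 and 125.9. KO 72 lay at -34.7, KO 79 at -4.0 and KO 75 at 73.4. Spearman's rho across genes between KO 72 and KO 79 was 0.985, against 0.912 and 0.943 for either with KO 75 (genes are not independent replicates). Every direction drawn from this group below is therefore that of the libraries labelled KO, and gene counts and the fold changes of the main genes are also given without KO 75.

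**Figure D1:**
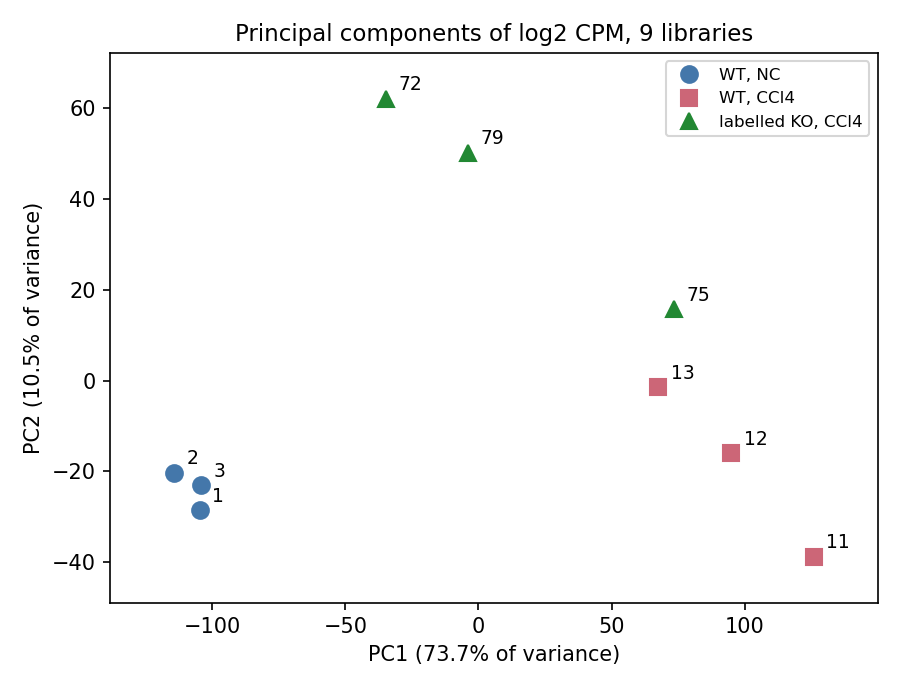
The 9 libraries on the first and second principal components of log2 CPM (arbitrary units), numbered by replicate. On the horizontal axis the library labelled KO 75 lies at 73.4, among the WT CCl4 libraries (67.6 to 125.9), and KO 72 and KO 79 lie at -34.7 and -4.0.

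In WT mice, CCl4 was accompanied by a loss of hepatocyte metabolic transcripts and a gain of transcripts of proliferation, inflammation and matrix. Cyp2e1, the cytochrome P450 that activates CCl4, fell from 8828 ± 1070 to 205 ± 64.3 CPM (SD, n = 3 each; log2 fold change -5.43 ± 0.64), and Pck1, the rate-limiting enzyme of gluconeogenesis, fell from 4210 ± 578 to 60.1 ± 21.3 CPM. Mki67, a marker of dividing cells, rose from 3.23 ± 1.12 to 233 ± 23.8 CPM, and Col1a1, a chain of type I collagen, rose from 2.76 ± 0.257 to 203 ± 92.8 CPM. Adgre1, the macrophage antigen F4/80, rose by 3.54 ± 0.68 on the log2 scale, Timp1, an inhibitor of matrix proteases, by 5.18 ± 0.85, and Tgfbr2 itself by 1.54 ± 0.39. Acta2, the smooth muscle actin of myofibroblasts, rose by 1.79 ± 0.55, a call that was lost without WT NC replicate 2 (1.92) or WT CCl4 replicate 12 (1.78). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p of these 8 genes lay between 6.84e-05 (Pck1) and 0.0215 (Acta2). Smad7, an inhibitor of TGF-beta signalling, had a log2 fold change of 0.17 (adjusted p = 0.596) and Alb, albumin, one of -0.68 (adjusted p = 0.165), and neither passed edgeR's test. Alb passed DESeq2's (adjusted p = 0.00532).

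Of 14134 genes tested, 7693 changed with CCl4 in WT mice, 4166 higher and 3527 lower. On FPKM, tested with limma on 10987 genes, 3844 were higher and 2054 lower. Among the genes chosen for the size of their change, with no overlap between the groups' libraries (which chance gives in 10% of genes), the 6 largest fitted rises were those of the cytokines Il10 and Tnf, the glycoprotein Gpnmb of lipid-laden macrophages, Lrrn4 and Upk3b, which the mesothelium expresses, and the pancreatic protease Cela3b. Gpnmb rose from 0.263 ± 0.109 to 1448 ± 663 CPM. Tnf had 1 count over the 3 WT NC libraries and 175 ± 175 CPM with CCl4, a ratio of 8520-fold (95% interval 1530 to 337000) that covers counting error only. Il10, Lrrn4, Cela3b and Upk3b had no count in the WT NC libraries and were at least 811-fold, 557-fold, 511-fold and 505-fold higher with CCl4, against a floor of 3 counts over that group. The 6 largest falls were those of Elovl3 (-8.24 on the log2 scale), a fatty acid elongase, Slc1a2 (-8.04), a glutamate transporter, Ugt2b38 (-7.93), Fitm1 (-7.16), Susd4 (-7.11) and Cyp4a12b (-6.83). The largest adjusted p among these 12 genes was 0.011 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

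Camera with a preset correlation of 0.01 called 27 of 37 gene lists, 18 higher and 9 lower, at adjusted p from 4.48e-13 to 0.0409. None was called once the correlation was estimated from the data (adjusted p = 0.39 with an estimated correlation at the smallest). Most metabolic lists were among those called lower. In each list below, the count in brackets is that adjusted over the list alone, and examples have their log2 fold change. Among cytochromes P450 and other drug-metabolising enzymes 29 of 33 (30) fell, with Cyp3a25 at -2.99 and Cyp2c37 at -5.47. Fatty acid oxidation genes fell in 25 of 28 (26), with Angptl4 at -2.77 and Vnn1 at -2.79, and nuclear-encoded subunits of the respiratory chain in 43 of 46 (45), with Cox6c at -1.86 and Ndufa1 at -1.64. Hepatocyte secretory and identity genes fell in 24 of 31 (25), with Tdo2 at -3.00 and Hpd at -3.05. Both ends of the liver lobule took part, with 20 of 26 (20) periportal genes (Sds at -2.67 and Pck1 at -6.13) and 14 of 23 (16) pericentral genes (Oat at -4.12 and Cyp2c29 at -3.43) lower. Bile acid genes fell in 18 of 22 (19), with Slco1b2 at -2.59 and Cyp27a1 at -2.64. All 16 tested genes of the male-biased liver list fell, with Hsd3b5 at -6.31 and Susd4 at -7.11. The circadian list fell in 9 of 18 (9), with Dbp at -2.81 and Ciart at -2.39, and rose in 3 of 18 (3).

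Proliferation and inflammation lists were among those called higher. Cell cycle genes rose in 34 of 35 (34), with Mcm6 at 3.72 and Mcm2 at 3.47. Every one of the 33 tested cytokine and chemokine genes rose, with Cxcl2 at 10.28 and Tnf as given above. Immediate early genes rose in 15 of 16 (15) (Fosb at 9.97 and Fos at 6.07), p53 targets in 15 of 19 (16) (Cdkn1a at 6.69 and Tnfrsf10b at 4.58) and interferon response genes in 19 of 32 (19) (Oas1a at 3.23 and Gbp2 at 3.10). NRF2 targets and glutathione enzymes rose in 13 of 23 (14) (G6pdx at 3.88 and Txnrd1 at 1.73), and fetal liver and liver cancer markers in 10 of 12 (10) (Ly6d at 4.41 and Golm1 at 3.99). Among matrix genes, collagens rose in 13 of 18 (14) (Col4a1 at 3.10 and Col4a2 at 2.86) and other matrix and protease genes in 29 of 33 (30) (Serpinh1 at 3.83 and Lamc1 at 2.14). TGF-beta targets rose in 13 of 19 (14) (Cdkn1a at 6.69 and Thbs1 at 7.57) and regulators of epithelial-mesenchymal transition in 7 of 12 (8) (Itga5 at 2.59 and Zeb2 at 3.66).

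Markers of other cell types moved with these groups. Macrophage markers rose in 24 of 26 (24) (Itgam at 5.89 and Marco at 3.29), endothelial markers in 20 of 25 (22) (Flt1 at 1.80 and Stab2 at 1.88) and stellate cell and myofibroblast markers in 13 of 20 (15) (Vim at 3.81 and Des at 2.34). Lymphocyte markers rose in 15 of 23 (17) (Jchain at 1.85 and Ighm at 2.20) and neutrophil markers in 11 of 13 (11), with Csf3r at 3.83 and Mpo at least 31.1-fold higher than the floor of 3 counts over the WT NC group. Genes of neighbouring tissue rose as well. Exocrine pancreas genes rose in 9 of 10 (10) (Ctrb1 at 10.52 and Pnlip at 9.02), and their mean stood 8.65, 7.03 and 1.92 log2 units above the WT NC mean in replicates 11, 12 and 13. Adipose and mesothelium genes rose in 5 of 6 (5), with Upk3b as given above and Msln, which had 1 count over the WT NC libraries, at a ratio of 736-fold (95% interval 132 to 29100).

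In the called lists besides the circadian list, at most 4 members went the other way (NRF2 targets lower, periportal genes higher). Camera did not call the lists of TGF-beta components (11 of 20 (11) higher and 3 of 20 (3) lower), BMP targets (4 of 13 (4) higher and 4 of 13 (4) lower), bile duct markers (6 of 16 (6) higher and 1 of 16 (1) lower), YAP targets (6 of 15 (6) higher and 2 of 15 (2) lower), acute phase (7 of 26 (7) higher and 4 of 26 (3) lower), ER stress (4 of 20 (4) higher and 7 of 20 (7) lower), lipogenesis (1 of 21 (1) higher and 4 of 21 (4) lower), cholesterol synthesis (1 of 24 (0) higher and 4 of 24 (3) lower), female-biased genes (2 of 10 (2) higher and 2 of 10 (2) lower) or erythrocyte genes (1 of 5 (1) lower). Of the 53 genes given as list examples, the largest adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.00375.

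**Figure D2:**
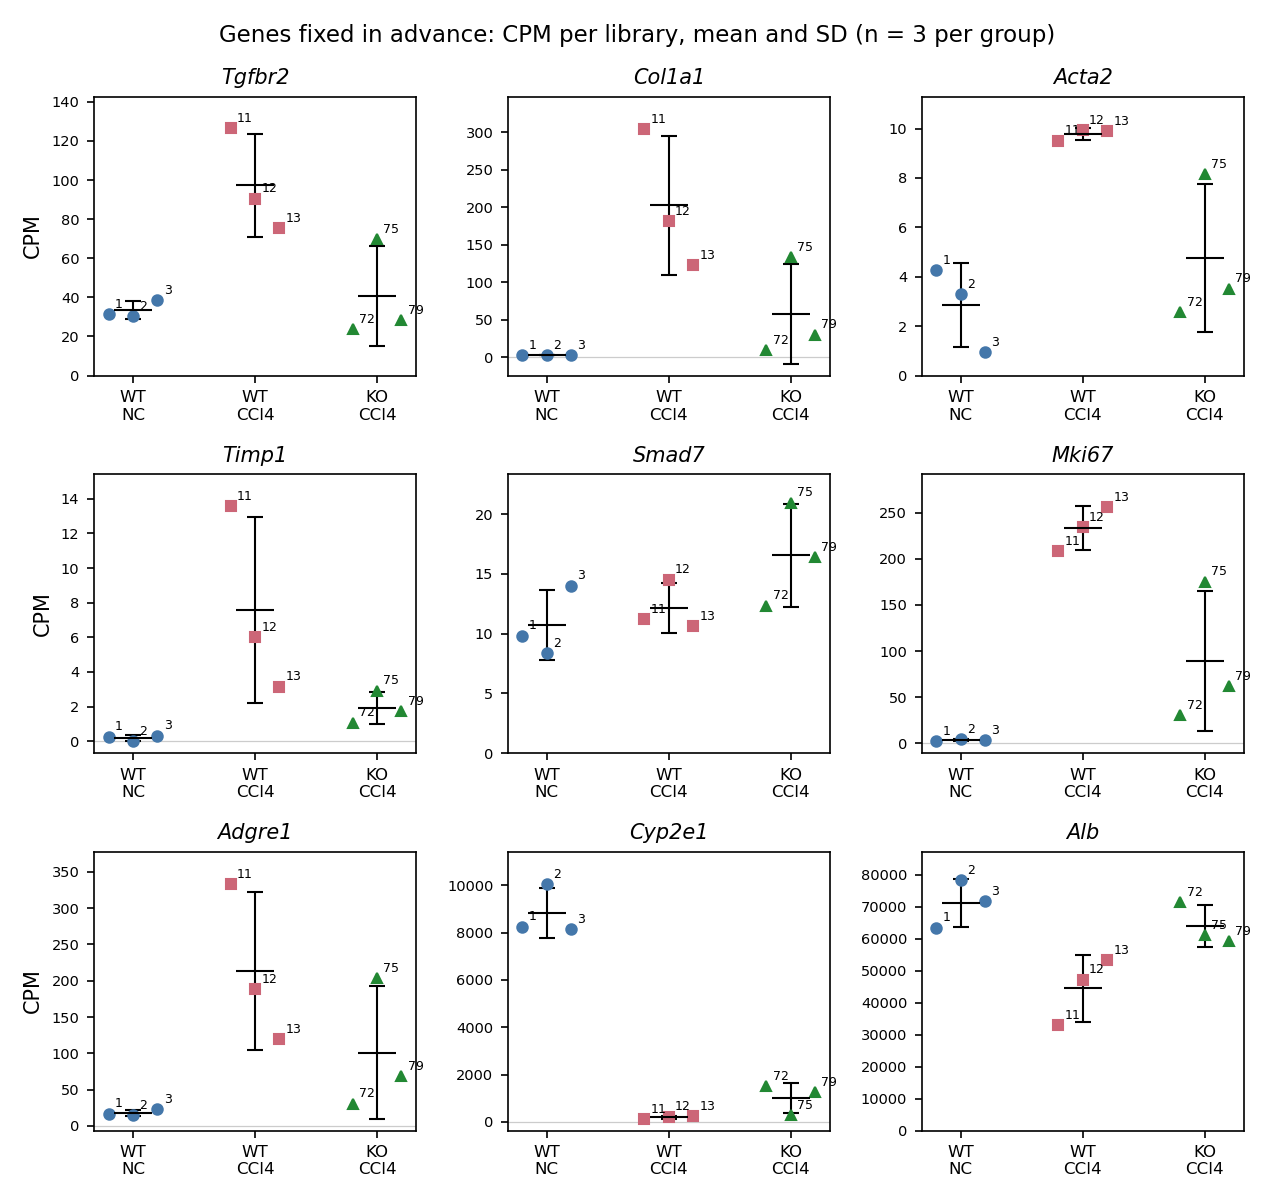
Expression in CPM (vertical axes, linear) of 9 genes fixed in advance in each library, numbered by replicate, with the mean and SD of each group of 3. Col1a1 stands at 123 to 304 CPM in the WT CCl4 libraries, at 133 CPM in KO 75, and at 9.48 and 30.1 CPM in KO 72 and KO 79.

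The comparison that the series names is that of KO with WT mice under CCl4. Some acute phase, drug-metabolising and female-biased genes were higher in the libraries labelled KO, and some cytokine and immediate early genes were lower (counts below). The serum amyloid genes Saa1 and Saa2, acute phase proteins made by hepatocytes, rose from 89.5 ± 9.20 to 1802 ± 466 CPM and from 54.6 ± 16.2 to 1886 ± 471 CPM (SD, n = 3 each; log2 fold changes 4.33 ± 0.29 and 5.11 ± 0.37). Tnf fell from 175 ± 175 to 0.917 ± 0.176 CPM. Cyp2e1 rose by 2.31 ± 0.56 on the log2 scale. Tnf varied widely among the WT CCl4 libraries, at 366, 134 and 24.2 CPM in replicates 11, 12 and 13. The adjusted p of these 4 genes lay between 0.000945 and 0.0496 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and in all 4 no library of one group overlapped the other group. Without KO 75 the log2 fold changes were 4.53 (Saa1), 5.27 (Saa2), -7.61 (Tnf) and 2.76 (Cyp2e1). Saa1 and Saa2 kept their calls without any single library. Tnf lost its call without WT CCl4 replicate 12 (-7.72), KO 72 (-7.41) or KO 79 (-7.65). Cyp2e1 lost it without any library except KO 75 (adjusted p = 0.0622 to 0.196 in edgeR's test).

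The fibrosis and macrophage genes fixed in advance did not pass that test with all libraries. Col1a1 had a log2 fold change of -1.81, Acta2 -1.04, Timp1 -1.97, Mki67 -1.39 and Adgre1 -1.08, at adjusted p between 0.0911 (Timp1) and 0.248 (Adgre1) in edgeR's test. Without the library labelled KO 75 all 5 passed, at -3.35, -1.68, -2.41, -2.34 and -2.11. Smad7 (0.45, and 0.25 without KO 75) and Alb (0.53, and 0.56) passed neither with nor without it.

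In all, 717 of 14134 genes changed between the libraries labelled KO and WT CCl4, 489 higher and 228 lower, and on FPKM 306 were higher and 395 lower. The count rested on single libraries. It was 5453 (2495 higher, 2958 lower) without KO 75, and these included all of the 717. It was 34 and 8 without KO 72 and KO 79, 36, 5 and 760 without WT CCl4 replicates 11, 12 and 13, and 86, 96 and 107 without WT NC replicates 1, 2 and 3, which enter through the shared estimate of the spread.

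The largest rises among genes whose libraries did not overlap were those of Cyp2c38 (5.42), Saa2 (5.11), Orm3 (4.87), an acute phase protein of the orosomucoid family, Csrp3 (4.68), Cyp4a12b (4.52) and Elovl3 (4.34). Without KO 75 these were, in the same order, 5.95, 5.27, 5.15, 5.11, 5.08 and 4.89. The largest falls were those of Fosl1, an AP-1 transcription factor, Tnf (-7.56), the endothelial selectin Sele (-5.86), Il10 (-5.62), Cd83 (-5.61) and Ifnb1. Without KO 75 Tnf, Sele, Il10 and Cd83 were at -7.61, -5.79, -5.82 and -5.70, while without WT CCl4 replicate 11 Sele, Il10 and Cd83 were at -4.48, -4.30 and -4.44. Ifnb1, the interferon beta gene, had no count in the libraries labelled KO and was at least 216-fold lower, against a floor of 3 counts over that group. Fosl1 had 1 count there and a ratio of WT CCl4 to KO of 284-fold (95% interval 50.5 to 11200, counting error only). Its fitted log2 fold change was -7.68 with all libraries, -5.97 without WT CCl4 replicate 11 and -9.48 without KO 75. Fitted log2 fold changes of these 12 genes had SE of up to 1.94, and their adjusted p lay between 0.000945 and 0.0493 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Only Saa2 among them kept its call without any single library. Cyp4a12b and Elovl3 lost it in 8 of the 9 fits without a library, and Cyp2c38, Sele, Il10, Cd83, Fosl1 and Ifnb1 in 7. Saa, Orm, Cyp2c and Cyp4a genes have near-identical copies, and their separate values are uncertain where the counting divided reads between the copies.

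Acute phase, sex-biased and BMP target lists were called higher by camera with the preset correlation. With an estimated correlation they were not (adjusted p = 0.103 to 0.617 with an estimated correlation). The brackets below give the count adjusted over the list alone, then the count without KO 75. Acute phase genes rose in 17 of 26 (21, 20), with Saa1 at 4.33 and Saa2 at 5.11, and the mean of the list stood 2.11, 1.99 and 2.08 log2 units above WT NC in KO 72, 75 and 79, against 0.38 to 0.56 in WT CCl4. Female-biased genes rose in 5 of 10 (8, 6), with Cyp17a1 at 2.97 and Cyp3a44 at 3.45, and their mean stood at 2.48, 2.97 and 2.78 in KO 72, 75 and 79, against 0.70 to 0.77 in WT CCl4. Male-biased genes rose in 2 of 16 (5, 12 of 17), with Cyp4a12b at 4.52 and Elovl3 at 4.34. Their mean was -5.56 in KO 75, below the WT CCl4 libraries (-5.05 to -4.44), and -2.76 and -3.10 in KO 72 and 79. The list of BMP targets and ligands rose in 4 of 13 (4, 5), with Hamp at 2.14 and Bmper, a secreted BMP-binding protein, at 1.68. Whether BMP signalling itself was higher was not tested. Hamp encodes the iron hormone hepcidin.

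Hepatocyte metabolic lists were called higher in the libraries labelled KO by camera with the preset correlation, but not with an estimated one (adjusted p = 0.427 to 0.575 with an estimated correlation). Fatty acid oxidation genes rose in 13 of 28 (24, 25), with Cyp4a14 at 3.61 and Cyp4a10 at 4.29. Drug-metabolising enzymes rose in 12 of 33 (24, 27) (Sult1d1 at 1.34 and Sult1a1 at 1.72), periportal genes in 10 of 26 (18, 18) (Sds at 1.92 and Pck1 at 2.91) and pericentral genes in 6 of 23 (9, 11) (Cyp2c29 at 2.92 and Oat at 1.82). Respiratory chain subunits rose in 8 of 46 (42, 42) (Cox6c at 1.20 and Ndufa9 at 0.87), hepatocyte secretory genes in 6 of 31 (22, 24), with the fibrinogen chains Fgb at 2.05 and Fgg at 2.03, and bile acid genes in 7 of 22 (12, 13) (Cyp27a1 at 1.75 and Abcb11 at 1.44). No gene of the lipogenesis list passed edgeR's test with all libraries (0 adjusted over the list alone, 12 higher at an unadjusted p under 0.05, 10 in DESeq2), and 17 of 21 rose without KO 75, whose mean for that list was -0.22 against 1.84 and 1.65 in KO 72 and 79. Of the cholesterol synthesis list 10 were higher at an unadjusted p under 0.05, 6 in DESeq2, 0 adjusted over the list alone, and 19 of 24 without KO 75.

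Inflammatory, proliferative and matrix lists were called lower by camera with the preset correlation, but not with an estimated one (adjusted p = 0.427 to 0.545 with an estimated correlation). Cytokine and chemokine genes fell in 11 of 33 (19, 23), with Tnf at -7.56 and Cxcl2 at -5.34, and immediate early genes in 3 of 16 (6, 7) (Fosb at -3.07 and Klf6 at -2.72). Cell cycle genes fell in 5 of 35 (14, 34) (Mcm4 at -1.81 and Mcm2 at -1.48), p53 targets in 2 of 19 (5, 13) (Mdm2 at -1.40 and Plk2 at -2.29) and NRF2 targets in 1 of 23 (1, 14) (Txnrd1 at -1.17). Matrix and protease genes fell in 5 of 33 (9, 28) (Timp3 at -1.70 and Mmp12 at -3.93), TGF-beta targets in 2 of 19 (2, 11) (Thbs1 at -3.78) and YAP targets in 1 of 15 (3, 5) (Ptpn14 at -1.66). Without WT CCl4 replicate 11 Thbs1 was at -2.61, Klf6 at -1.97, Fosb at -2.3 and Plk2 at -1.64. Mcm4 (-1.88), Mcm2 (-1.58) and Txnrd1 (-1.21) moved slightly the other way. No collagen, TGF-beta component or gene of epithelial-mesenchymal transition passed edgeR's test with all libraries, while adjusted over the list alone 0, 6 and 2 fell. At an unadjusted p under 0.05 10, 7 and 5 were lower, in DESeq2 4, 6 and 4, and without KO 75 13 of 18, 10 of 20 and 5 of 12. Collagens and TGF-beta components also had members higher, 2 and 1 at an unadjusted p under 0.05, 1 and 1 in DESeq2, and 3 of 18 and 1 of 20 without KO 75, and 1 component was higher adjusted over the list alone.

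Macrophage, stellate cell, endothelial, and adipose and mesothelium lists were called lower by camera with the preset correlation, but not with an estimated one (adjusted p = 0.427 to 0.575 with an estimated correlation). With all libraries no macrophage, stellate cell, endothelial, or adipose and mesothelium marker passed edgeR's test, while adjusted over the list alone 0, 0, 6 and 4 fell. At an unadjusted p under 0.05 3, 3, 9 and 4 were lower, and in DESeq2 2, 2, 6 and 4. Without KO 75 22 of 26, 14 of 20, 20 of 25 and 5 of 7 fell, and 1 of the last 7 rose. The macrophage mean stood 0.93, 3.62 and 2.04 log2 units above WT NC in KO 72, 75 and 79, and 2.84 to 4.06 above it in WT CCl4. The exocrine pancreas mean stood, in the same order, at 3.18, 5.96 and 4.18, above WT NC.

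Camera with the preset correlation called 28 of 37 lists in this comparison, 13 higher and 15 lower, at adjusted p from 3.76e-15 to 0.0431. None was called with an estimated correlation, where the smallest values were those of the acute phase and female-biased lists (adjusted p = 0.103 with an estimated correlation for each). Not called, with the same brackets, were the circadian list (3 of 18 (5, 6) higher and 4 of 18 (7, 6) lower), ER stress (0 of 20 (1, 3) higher and 2 of 20 (2, 2) lower), interferon response (4 of 32 (5, 5) higher and 0 of 32 (3, 12) lower), fetal liver (2 of 12 (2, 2) higher and 0 of 12 (1, 4) lower) and neutrophil lists (1 of 13 (1, 1) higher and 0 of 13 (0, 3) lower). At an unadjusted p under 0.05, 4 ER stress genes were higher, and 7 interferon, 1 fetal liver and 3 neutrophil genes lower, and in DESeq2 2, 5, 1 and 2. Lymphocyte, bile duct, pancreas and erythrocyte lists were not called either and had no member lower in edgeR's test, with 1, 3, 3 and 0 lower at an unadjusted p under 0.05 and 0, 2, 1 and 0 in DESeq2. Without KO 75 4 of 23 lymphocyte, 8 of 17 bile duct and 1 of 10 pancreas genes fell. Without it camera with the preset correlation also called the bile duct list (adjusted p = 0.0494), and no longer called the BMP (adjusted p = 0.0619) or the adipose and mesothelium list (adjusted p = 0.0525). Of the 55 genes that the rule named for this comparison besides Tgfbr2, 45 lost the call in at least 1 of the 9 fits without a library. The list examples given here had an adjusted p of at most 0.0488 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All of them also passed without KO 75, and the fold change that moved most was that of Mmp12 (-5.29).

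**Figure D3:**
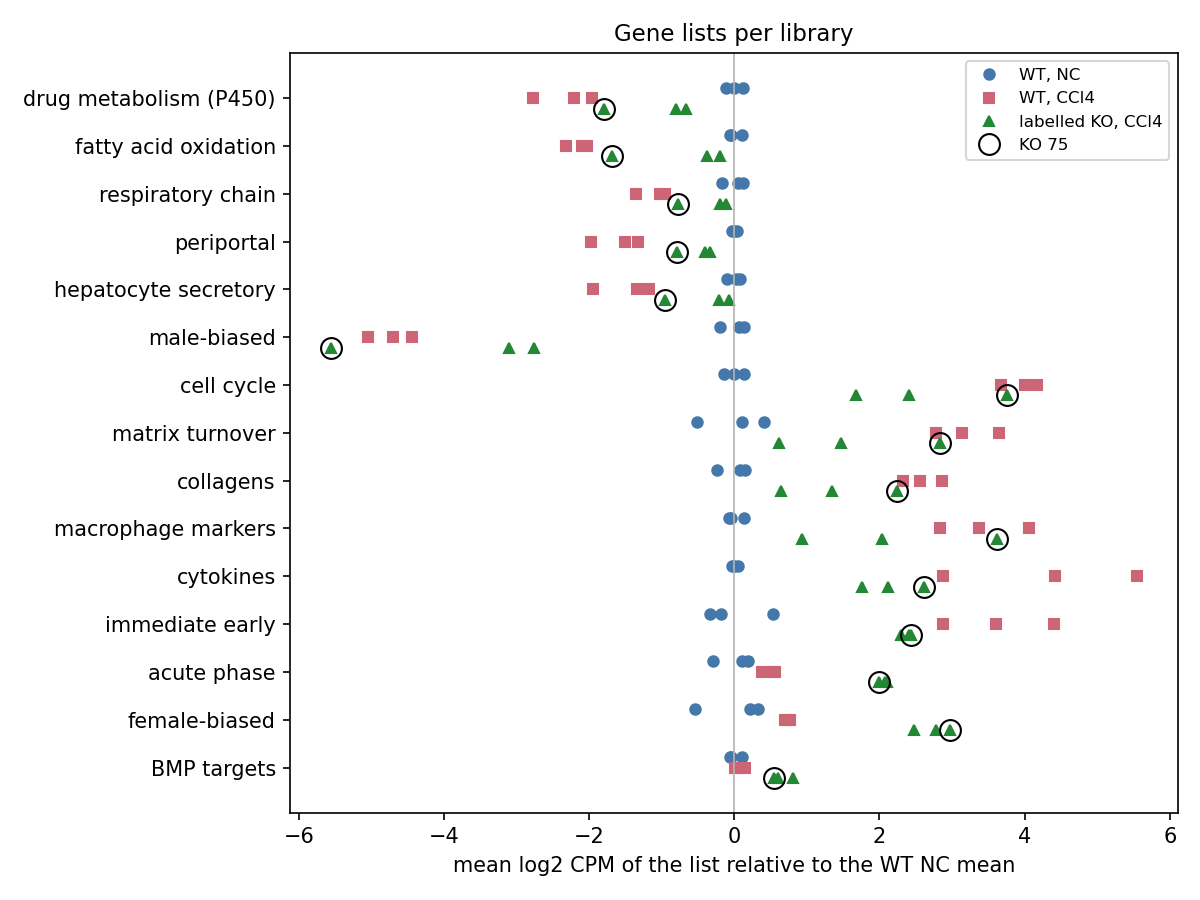
Mean log2 CPM of 15 gene lists in each library relative to the WT NC mean (horizontal axis, log2 units), 1 point per library, with the library labelled KO 75 circled. KO 75 lies near the WT CCl4 libraries for macrophage markers (3.62) and cell cycle genes (3.76), and with KO 72 and KO 79 for acute phase genes (1.99).

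Of the genes called both with CCl4 in WT mice and between KO and WT, most went in opposite directions. The 5 genes with the clearest opposite changes were Sds (-2.67 with CCl4, 1.92 in KO against WT), Pck1 (-6.13 and 2.91) and Cth (-2.20 and 1.95), enzymes of amino acid breakdown, gluconeogenesis and cysteine synthesis, Cyp4a14 (-4.65 and 3.61), a fatty acid hydroxylase, and Nlrp12 (-4.29 and 2.54). Without KO 75 the values in KO against WT were 1.91, 3.07, 2.10, 3.98 and 2.64. In KO against WT, Sds kept its call without any single library. Without WT CCl4 replicate 12 Pck1 (2.97), Cth (1.98), Cyp4a14 (3.58) and Nlrp12 (2.53) lost theirs, without KO 79 Pck1 (2.88), Cth (1.90) and Cyp4a14 (3.46), and without WT CCl4 replicate 11 Cyp4a14 (3.47). Of 631 genes called in both comparisons, 609 went in opposite directions (206 higher and then lower, 403 lower and then higher) and 22 in the same direction. Which of these kinds was larger turned over on FPKM (366 and 242), without KO 75 (2626 and 2043) and without WT CCl4 replicate 13 (384 and 290). Independent lists of these sizes would share 189.2 genes in opposite and 201.0 in the same direction. Both comparisons use the WT CCl4 libraries, with opposite sign. In 20 simulations of unchanged groups that shared them, a mean of 0.05 genes was called in both in opposite directions. No gene changed with CCl4 there, so hardly any could be called. The 0.05 therefore does not measure what sharing adds to the 609. The covariance of the fold changes across genes was -0.096 in the simulations, against -1.381 observed (correlations -0.498 and -0.749). Of all genes tested, 81.2% had opposite signs, against a mean of 66.7% in these simulations. The 3 shared libraries were too few to divide between the comparisons with 2 in each, so part of the excess may come from sharing. The count of opposite genes was 4669 without KO 75, 22 and 3 without KO 72 and KO 79, 24, 1 and 674 without WT CCl4 replicates 11, 12 and 13, and 64, 63 and 73 without WT NC replicates 1, 2 and 3. That of genes in the same direction was 71 without KO 75 and between 3 and 10 without any other library except WT CCl4 replicate 13 (19).

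The share of the CCl4 change left in the libraries labelled KO was measured on other libraries than those that chose the genes. Over the 9 ways to leave out 1 WT NC and 1 WT CCl4 library it averaged 53.6% (45.2% to 63.0%), at 54.2% for genes that rose and 51.7% for genes that fell. KO 75 kept 88.0%, against 29.7% in KO 72 and 43.1% in KO 79. No test was made of this share.

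The libraries labelled KO were last compared with WT NC, where genotype and CCl4 differ together. Most cell cycle genes and some macrophage and matrix genes stayed above WT NC, and most male-biased genes stayed below (counts below). Mki67 was 4.79 ± 0.63 log2 units higher, Col1a1 4.38 ± 0.89, Timp1 3.21 ± 0.84 and Adgre1 2.46 ± 0.65, and Cyp2e1 was lower (-3.12 ± 0.58), at adjusted p between 0.00235 (Mki67) and 0.0275 (Adgre1) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without KO 75 Mki67 was at 3.84, Col1a1 at 2.84 and Cyp2e1 at -2.67. Timp1 (2.76) and Adgre1 (1.43) did not pass without KO 75, and each also lost the call without WT NC replicate 1 (3.42 and 2.41), 2 (2.68 and 2.32) or 3 (3.75 and 2.64). Timp1 lost it without KO 79 (3.27), and Col1a1 without WT NC replicate 1 (4.32). Tgfbr2 (0.28, and -0.36 without KO 75), Acta2 (0.76 and 0.12), Smad7 (0.62 and 0.42) and Alb (-0.15 and -0.12) did not pass. The 3 largest rises were those of Gpnmb (9.91, and 7.89 without KO 75), Chil3, a macrophage chitinase-like protein with 2 counts over the WT NC group and a ratio of 484-fold (95% interval 134 to 4000), and Upk3b, which was at least 82.8-fold higher against a floor of 3 counts over the WT NC group. Without KO 75 the fitted log2 fold change of Chil3 went from 8.6 to 7.7 and that of Upk3b from 9.56 to 8.38. The 3 largest falls were those of Hsd3b5 (-8.37), a male-specific steroid enzyme, Ugt2b38 (-6.68) and Clec2h (-6.36), at -7.82, -6.15 and -6.52 without KO 75.

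Between the libraries labelled KO and WT NC 3247 genes differed, 1978 higher and 1269 lower, and on FPKM 696 were higher and 1015 lower. The count was 1370, 1264 and 1601 without WT NC replicates 1, 2 and 3. It was 3679, 2503 and 2045 without KO 72, 75 and 79, and 3430, 2209 and 3134 without WT CCl4 replicates 11, 12 and 13. Without KO 75 1437 were higher and 1066 lower. The brackets again give the count adjusted over the list alone, then that without KO 75. Higher were 30 of 35 (30, 28) cell cycle genes, 19 of 26 (24, 11) macrophage, 8 of 13 (11, 8) neutrophil, 7 of 23 (8, 4) lymphocyte, 15 of 25 (17, 13) endothelial and 4 of 20 (8, 0) stellate cell markers, 12 of 18 (14, 7) collagens, 16 of 33 (21, 10) other matrix genes and 4 of 19 (6, 2) TGF-beta targets. Acute phase genes rose in 18 of 26 (20, 21), cytokines in 14 of 33 (24, 9), immediate early genes in 7 of 16 (9, 10), interferon response genes in 15 of 32 (17, 9), p53 targets in 6 of 19 (10, 4), fetal liver genes in 10 of 12 (11, 9), lipogenesis genes in 9 of 21 (10, 14) and female-biased genes in 6 of 10 (7, 6). Pancreas genes were higher in 2 of 10 (8, 1) and adipose and mesothelium genes in 4 of 6 (5, 3 of 7). Lower were 12 of 16 (15, 14 of 17) male-biased genes, 11 of 33 (16, 13) drug-metabolising enzymes, 10 of 18 (11, 9) circadian genes, 8 of 22 (12, 9) bile acid, 8 of 26 (9, 9) periportal, 7 of 23 (7, 7) pericentral, 6 of 28 (6, 6) fatty acid oxidation, 3 of 46 (0, 1) respiratory chain and 2 of 31 (1, 1) hepatocyte secretory genes. Some members of the lower lists were higher, 4 of 18 (4, 5) circadian and 3 of 26 (5, 2) periportal genes, and in each other list above at most 1 went against the rest with all libraries. Camera with the preset correlation called these 28 lists, 19 higher and 9 lower, at adjusted p from 6.33e-13 to 0.0329, and none was called with an estimated correlation (adjusted p = 0.21 with an estimated correlation at the smallest). The other 9 lists were not called. Without KO 75 camera with the preset correlation no longer called the TGF-beta target, stellate cell, hepatocyte secretory, or adipose and mesothelium lists (adjusted p = 0.104 to 0.312), and called the cholesterol synthesis list (adjusted p = 1.2e-06).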

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

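The fit without mitochondrial genes was chosen only after seeing the data. With CCl4 in WT, 7693 genes changed, 4899 against a fold change of 1.5 and 6237 to 8522 without single replicates. Between KO and WT under CCl4 the 717 genes became 2766 in DESeq2, 30 in a fit of only the 6 samples, 54 against a fold change of 1.5, and 5 (without WT CCl4 replicate 12) to 5453 (without KO 75), and the cause was not tested. For KO with CCl4 against WT with NC the 3247 genes became 1711 on FPKM, 1214 against a fold change of 1.5, and 1264 (without WT NC replicate 2) to 3679 (without KO 72). The other counts of the 3 comparisons, with other size factors, no filter or no mitochondrial genes, lay within 1.5 times. On FPKM, where the scaling, the test, the pseudocount and the gene filter all differ, the median log2 fold change of all genes was 0.21 in the first comparison and -0.19 in the second, against 0.04 and -0.03.

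The lists called by camera fell from 27, 28 and 28 to 0, 0 and 0 with an estimated correlation, while fry, which asks whether a list's genes move one way and not whether they differ from other genes, called 30, 13 and 18. Genes called in opposite directions in the first 2 comparisons numbered 609, with 2347 in DESeq2, 16 in a fit of only the 6 samples, 33 against a fold change of 1.5 and 1 to 4669 without single replicates. Those in the same direction numbered 22, with 44, 5, 7 and 3 to 71 in the same order. The share of the CCl4 change left was 53.6%, with 54.6% for genes changed over 2-fold and 53.6% with other size factors.

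Tgfbr2 between KO and WT under CCl4 (-1.26) passed in DESeq2 (-1.27, adjusted p = 0.0172) and without KO 75 (-1.91), with a range without single replicates of -1.91 to -0.98 (without KO 72). Against WT NC it was 0.28, with a range of -0.36 (without KO 75) to 0.56 (without KO 72), the only sign change among the named genes. Of the other genes named, 72 of 74 kept their call under every alternative in the first comparison, 5 of 55 in the second (Saa1, Saa2 and Sds called, Alb and Smad7 not) and 10 of 15 in the last. In the last, Col1a1, Timp1, Adgre1, Gpnmb and Upk3b lost the call on FPKM. The causes were not tested.

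No paired analysis was possible because the groups share no replicate numbers. A pseudocount of 0.1 was not run, since the table holds counts. At this depth and spread, most 2-fold changes would be missed between KO and WT, by the simulated counts.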

Other observations

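The genes of the next paragraph, and every test below except that of the position of KO 75 between the groups and those of other splits of the samples, were chosen only after the results were seen.

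Of the 631 genes called both with CCl4 in WT and in KO against WT, 22 moved the same way, and 6 of these are clock genes. The 5 others given here were picked from the rest and stand for no tested group. Lcn2, the iron-binding lipocalin of the acute phase, rose by 5.07 and by a further 2.10 on the log2 scale (SE 0.30 and 0.26), Orm2, an orosomucoid, by 2.90 and 2.91, and Apoa4, an apolipoprotein, by 1.58 and 1.97. Bcl6, a transcriptional repressor, fell in both (-1.87 and -1.33), as did Serpina1e, an alpha-1-antitrypsin gene (-2.45 and -1.66). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the largest adjusted p of these 5 genes was 0.0272 (Apoa4), and all passed without KO 75. Without WT CCl4 replicate 12, and without KO 79, 1 gene in all was called higher in both comparisons and 2 lower in both, so at least 2 of Lcn2, Orm2 and Apoa4 lost a call there.

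Of the sex-chromosome list, 0 of 4 genes tested rose and 2 fell with CCl4 in WT, none passed between KO and WT under CCl4 in edgeR's test (0 at an unadjusted p under 0.05 and 0 in DESeq2), and 1 fell in KO against WT NC. The counts adjusted over the list alone were the same. The median log2 fold change of the 4 genes was -0.23, 0.12 and -0.15 in the 3 comparisons. The mean of the list lay between -0.31 and 0.07 log2 units of the WT NC mean in every library. No difference in sex between the groups was seen in these values, and they do not give which sex the animals had.

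The library labelled KO 75 lay at 73.4 on the first principal component, among the WT CCl4 libraries. A wrong label on a sample of that group is argued against by the acute phase list, which stood at 1.99 in KO 75 and at 0.38 to 0.56 in the WT CCl4 libraries. The female-biased list (2.97 against 0.70 to 0.77), Nr1d1 (0.85 against 3.38 to 5.80 log2 CPM) and mt-Atp6 relative to mt-Co2 (0.150 against 1.18 to 1.28) likewise set it apart from them, although a WT animal treated or collected with the KO animals stays open. These were picked after the results, KO 75 included, were seen. Without KO 75, camera with the preset correlation still called the acute phase and female-biased lists in KO against WT (adjusted p = 8.26e-08 and 0.00122). Other lists placed KO 75 among the WT CCl4 libraries, such as macrophage (3.62 against 2.84 to 4.06) and cell cycle (3.76 against 3.68 to 4.17). A smaller share of hepatocytes would raise markers of the other cell types alike. All 6 lists rose over KO 72 and 79, by 0.50 (lymphocyte) to 2.13 (macrophage). That gap was 4.17 times the mean SD of the 6 lists among the WT CCl4 libraries. The lymphocyte and macrophage lists themselves varied more there (SD 0.71 and 0.61), so the test cannot decide on a smaller share of hepatocytes. On genes in which no change with CCl4 was detected, some of which may still have moved with it, KO 75 lay 27.8% of the way from WT CCl4 to KO 72 and 79 (17.8%, 28.4% and 37.1%, with left-out WT CCl4 libraries at -22.0%, 5.5% and 27.2%). This left open whether the animal was WT or KO. Whether Tgfbr2 was left intact in this animal cannot be told apart from deletion, since Tgfbr2 relative to endothelial and macrophage markers was -0.15, below WT CCl4 (0.32 to 0.39) and between KO 72 and 79 (0.05 and -0.32), but relative to endothelial markers alone it was 0.75, closer to WT CCl4 (0.91 to 1.42) than to KO 72 and 79 (0.01 and 0.13). Relative to macrophage markers alone it was -1.02, below WT CCl4 (-0.61 to -0.14) and below KO 72 and 79 (0.10 and -0.75).

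mt-Atp6, a subunit of the mitochondrial ATP synthase, stood at 1.18 to 1.28 counts per count of mt-Co2 in the WT CCl4 libraries and WT NC replicate 2 (1.23), and at 0.150 to 0.204 in the other 5 libraries. Genotype is argued against by the 2 WT libraries in the low set (WT NC replicates 1 and 3). Reads moved to the nuclear copy Gm10925 are argued against by the sum of both genes, which still differed 4.54 times between the sets, and a batch that affects all mitochondrial genes by the other 12, of which 0 split the libraries likewise by over 1.5 times. Among these 12, mt-Co2 was the divisor and could not split them. A difference in mitochondrial DNA sequence, or in how reads over this gene were aligned or counted, stays open and was not tested. mt-Atp6 passed in neither comparison (1.92, adjusted p = 0.0601, and -2.84, adjusted p = 0.0633, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

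Dbp and Nr1d1, clock-controlled genes, were lower in the libraries labelled KO than in WT CCl4 (-3.05 and -4.29, and -2.93 and -4.38 without KO 75), on top of a fall with CCl4 in WT (-2.81 and -1.69). Of the 8 clock genes grouped with Dbp, Nr1d2 was also lower in KO against WT (-2.19), and the median of the 8 was -0.97. Tef (-0.56), Per1 (-0.79), Per3 (-1.15), Hlf (0.22) and Per2 (0.16) did not pass edgeR's test there. A weaker response to CCl4 in the libraries labelled KO is argued against only for the clock genes called in both comparisons (6 of 13). In 6 of 6 they moved the same way, against 3.49% of all genes called in both, which include these 6. The clock genes were picked after this was seen and are not independent replicates, so the difference in shares is no independent test. Another time of day at collection may account for the lower Dbp and Nr1d1, as 5 clock genes of opposite phase (Arntl, Npas2, Clock, Nfil3 and Cry1) had a median of 1.26 in KO against WT. The SE of that median, 0.76, was taken over the 5 genes and holds no spread between samples. Npas2 and Nfil3 did not pass edgeR's test in either comparison. With CCl4 in WT the 5 genes of opposite phase had a median of 0.82, and the 8 grouped with Dbp one of -1.34. Collection time may therefore differ in that comparison too. No collection time is given in the sources used here, and time and group cannot be separated in this design. An effect of genotype or CCl4 on the clock therefore stays open and untested. Whether a difference in time also moved other genes in these comparisons was not tested.

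With 3 samples against 3 there are 10 splits, which cannot give a share under 0.05. In edgeR's test the real split gave 7693, 717 and 3247 genes in the 3 comparisons and the highest of the other splits 0 in each, so 1 of 10 splits gave as many. Each other split mixed libraries of both groups, which widens the spread within a set where the groups differ. Few calls could come from such splits, so the 0 cannot decide on chance.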
